A study of Mus musculus with 18 samples.

How the data were processed

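Gene expression was measured in 18 libraries from mouse stem cells, 3 each of EpiSC, D3, D5, D8, rES and ESC. Per the labels, total RNA was depleted of ribosomal RNA with probes and RNase H, made into libraries with a VAHTS kit and sequenced as paired 150-base reads on a HiSeq X instrument. The authors demultiplexed with bcl2fastq, trimmed with Trim Galore and aligned with HISAT2 to mm10, without versions. The deposited table gives expected counts, 1 whole number per gene symbol and library, not scaled between libraries. The counting program, the annotation and the strand setting are not given in the sources used here, so genes that overlap on opposite strands and genes of near-identical sequence may be counted wrongly. Low counts bunch at 4 and 8: the median library had 157 genes with a count of 3, 314.5 with 4 and 105.5 with 5, and 152.5, 163 and 109 genes with counts of 7, 8 and 9. The counts were used as deposited, and as an alternative divided by 4 and rounded. The deposited reads were not used here. No library was left out.

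The table as used here held 25239 symbols, none of them mitochondrially encoded. Gene positions came from GENCODE vM21 on GRCm38, the assembly also called mm10. Groups were taken from the labels, which say nothing of growth conditions. Replicate numbers were checked for pairing across groups: over 45 same-number pairs the median correlation of residuals was 0 (-0.061 to 0.053), and 7 of 18 libraries matched best with their own number, so the fit took the replicates as unpaired.

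Counts were fitted with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3, all 18 libraries in 1 fit, after filterByExpr, which kept 17545 genes, and with TMM scaling, whose factors were 0.945 to 1.05. The common biological coefficient of variation was 0.167. Each comparison used edgeR's quasi-likelihood F test of the null hypothesis of no difference, with Benjamini-Hochberg adjustment over the genes of that comparison and a threshold of 0.05 on adjusted p. Standard errors of log2 differences were computed as the absolute log2 difference divided by the square root of F, which is approximate. Log2 values used a prior count of 2. A gene was counted as 2-fold different when it was called and its log2 difference was at least 1 either way. Genes without overlap are those whose 3 libraries of one group all lay above or below the 3 of the other, which chance alone gives for 10%.

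Depth set the floor. With 58.4 to 101.6 M counts per library, the floor of 12 counts was 0.156 CPM at D8, 0.188 in EpiSC, 0.189 at D3, 0.190 at D5 and in ESC and 0.196 in rES. Folds against a group without counts are bounds from that floor and cover counting error only. For genes with few counts levels are given instead of folds. The steps were tested on simulated data made from the mean levels and spread over all libraries, in units of 4 counts. Changes were placed in ESC and tested against EpiSC. The changed genes were drawn from those with higher counts, so recovery of genes with few counts was not tested. Of genes changed 1.5-fold, 2-fold and 4-fold, 55.2%, 79.1% and 97% were recovered, and 4.9% of calls were false. Only 67, 67 and 66 of 17167 simulated genes were changed, up and down about equally. The real comparison called 11802 genes, so these rates may not hold for it, and scaling under such wide change was not tested. A list of 20 genes raised 1.5-fold was called by the list test, as were 3 of 100 random lists at the 0.05 level. Genes were simulated independently of each other, so this does not cover lists whose members move together.

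The comparisons were each group of the transition and ESC against EpiSC, rES against ESC, and the steps D3 to D5, D5 to D8 and D8 to rES. Genes were named by a rule: 12 genes, Cpt1a, Cpt2, Pou5f1, Sox2, Nanog, Klf4, Esrrb, Zfp42, Fgf5, Otx2, Pou3f1 and Dnmt3b, in every comparison with EpiSC and in rES against ESC; the 5 largest differences each way among called genes without overlap and with at least 10 CPM in a group, symbols that begin with Gm or end in Rik being skipped; and up to 4 called members of each described list with at least 5 CPM. Some genes that the rule names are not reported here. The 12 genes, the lists and the comparisons were chosen before the data were examined.

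The lists were naive pluripotency factors and markers; primed pluripotency markers; shared pluripotency factors; fatty acid oxidation; fatty acid synthesis, elongation and desaturation; phospholipid synthesis and remodelling; triglyceride and lipid droplets; sphingolipid synthesis and turnover; cholesterol synthesis; glycolysis; nuclear-encoded oxidative phosphorylation; mitochondrially encoded genes; DNA methylation machinery; germline genes; BMP-SMAD targets and related regulators; FGF-ERK response genes; WNT target genes; LIF-STAT3 pathway genes; epithelial markers; mesenchymal markers; mesoderm and definitive endoderm; primitive endoderm; neural progenitors; trophoblast; feeder fibroblasts; 2-cell-like genes; imprinted genes; p53 target genes; integrated stress response; and line identity (sex-linked). Each was tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 261 tests, 29 lists in 9 comparisons. Because members of a list move together, the test was repeated with an estimated correlation. Of the 261 tests 122 passed at the preset value and 30 with an estimated correlation. List members were also adjusted over the list alone. A median with genes at their bound puts genes without counts in a group at the floor.

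Positions between EpiSC and ESC are projections of log2 CPM on the line between the 2 group means. Principal components used the 2000 most variable genes. Genes raised or lowered transiently were called and at least 2-fold different from both EpiSC and rES in the same direction at D3, D5 or D8, and lists were tested among them with Fisher's exact test and Benjamini-Hochberg adjustment. To gauge shared controls, 20 sets of unchanged groups were simulated. Calls were also counted for all 10 ways of splitting each 6 libraries into 3 and 3.

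Alternatives were the removal of 1312 structural RNA symbols, a replicate block, an estimated correlation, no filter, a stricter filter of 1 CPM in 3 libraries, all tested genes on the axis, each 2 groups fitted alone, a prior count of 0.5, each library left out in turn, RLE scaling, limma's fry in place of camera and the Wald test of DESeq2 1.42.0. Division of the counts by 4, and transient genes without day 8, were added after the data were seen. RLE scaling moved the median of all genes by at most 0.092. Tables and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.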

Results

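RNA was sequenced from 18 mouse stem cell libraries, 3 in each of 6 groups, to follow cells from primed to naive pluripotency. EpiSC, labelled primed stem cells, were day 0. D3, D5 and D8, labelled transient, were days 3, 5 and 8. The rES, labelled naive, were the cells obtained at the end, and ESC were mouse embryonic stem cells for reference. Libraries were made from total RNA after removal of ribosomal RNA. The deposited expected counts summed, in megacounts (M), to 61.9, 63.9 and 65.8 M in EpiSC replicates 1 to 3 and to 58.4, 63.3 and 68.7 M at D3. They summed to 65.2, 63.2 and 61.2 M at D5, 65.0, 101.6 and 63.5 M at D8, 61.4, 58.4 and 63.5 M in rES and 59.0, 60.1 and 70.8 M in ESC. Of 25239 gene symbols, 21120 had a count in some library and 17545 were tested. No mitochondrially encoded gene was among the symbols used here, so that list had 0 members. Genes above 0 numbered 15993 ± 266 in EpiSC and 18015 ± 311 at D8, the lowest and highest of the 6 groups. Libraries of the same group correlated at 0.9886 to 0.9969. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples. Levels are counts per M (CPM) as mean ± SD of 3 libraries, and log2 differences carry an approximate standard error.

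The first question was how the naive and primed reference states differed, ESC against EpiSC. Cpt1a, which forms the acylcarnitines that enter mitochondria for fatty acid oxidation, averaged 192 ± 3.11 CPM in ESC and 1.62 ± 0.186 CPM in EpiSC (log2 difference 6.89 ± 0.14, adjusted p = 8.09e-17). Cpt2, which turns acylcarnitines back into acyl-CoA inside mitochondria, was lower in ESC at 26.4 ± 0.417 against 49.5 ± 3.84 CPM (log2 difference -0.91 ± 0.12, adjusted p = 4.11e-06). The naive factors Nanog, Klf4 and Esrrb averaged 1114 ± 24.7, 311 ± 25.3 and 782 ± 27.6 CPM in ESC and 40.9 ± 6.70, 6.50 ± 1.43 and 3.26 ± 1.14 CPM in EpiSC, with adjusted p of 1.03e-13, 1.62e-13 and 5.26e-13. Zfp42, a naive marker without a count in EpiSC, stood at 318 ± 4.32 CPM in ESC, at least 1690-fold higher (adjusted p = 5.89e-14). Where a group had no count, such bounds take 12 deposited counts per library as the floor.

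Primed genes went the other way. Fgf5 fell from 64.2 ± 5.07 CPM in EpiSC to 0.0870 CPM in ESC (adjusted p = 1.59e-10). Otx2, Pou3f1 and the de novo DNA methyltransferase Dnmt3b stood at 4.92 ± 1.18, 1.57 ± 0.245 and 71.5 ± 2.13 CPM in ESC and at 85.2 ± 0.987, 195 ± 33.9 and 1248 ± 46.3 CPM in EpiSC (log2 differences -4.12 ± 0.33, -6.96 ± 0.20 and -4.12 ± 0.10). Pou5f1 was level at 329 ± 2.43 and 331 ± 63.1 CPM (adjusted p = 1.0). Sox2 averaged 279 ± 29.0 and 189 ± 27.5 CPM and missed the threshold at adjusted p = 0.0697. It passed with RLE scaling at 0.0298, with a replicate block at 0.0493, with counts divided by 4 at 0.0390 and with the 2 groups fitted alone at 0.000207. The largest rises beside Zfp42 were Rbmxl2, Nr0b1, Dmgdh and Bhmt, without a count in EpiSC and at 116 ± 6.56, 111 ± 11.1, 107 ± 5.50 and 89.1 ± 3.90 CPM in ESC. Klhl4, Enpp2, Jakmip2, Npcd and Cysltr1 had no count in ESC and 288 ± 10.3, 52.8 ± 5.64, 29.4 ± 1.06, 13.8 ± 10 and 13.3 ± 1.58 CPM in EpiSC. Klhl4 was at least 1520-fold lower.

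**Figure D1:**
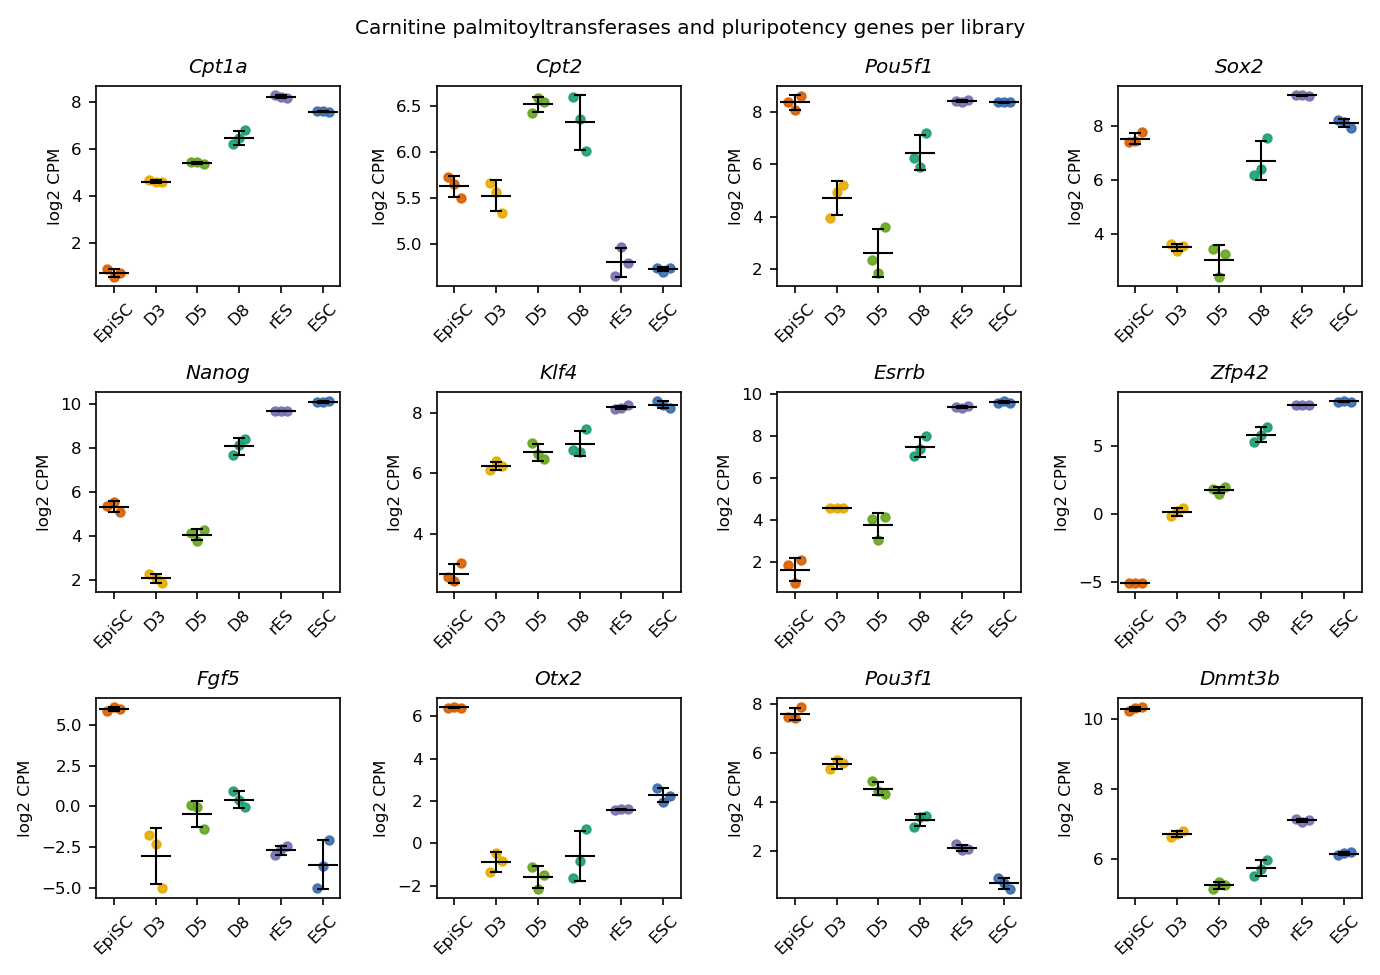
Log2 CPM of 12 genes chosen before the data were examined, 1 point per library and bars for mean ± SD, in EpiSC, D3, D5, D8, rES and ESC (n = 3 each). Cpt1a rose at every step from 1.62 CPM in EpiSC to 299.8 CPM in rES, while Pou5f1, Sox2 and Nanog were lower at D3 and D5 than in EpiSC and in rES.

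Of 21 naive factors and markers, 20 were higher in ESC and Gbx2 alone was lower (camera adjusted p = 1.03e-25; median log2 7.91, or 7.46 with 4 genes without counts at their bound). These counts were the same adjusted over the list alone, as were all below for which no other count is given. Tcl1 and Spic, 33.1 ± 2.96 and 27.0 ± 2.22 CPM in ESC, had no count in EpiSC. Of 16 primed markers 14 were lower, 15 adjusted over the list alone, and Nodal was higher (adjusted p = 2.98e-12). Sox11 fell from 185 ± 8.47 to 9.69 ± 0.618 CPM. The 11 shared pluripotency factors split, 4 higher and 2 lower (adjusted p = 0.267). Dppa2 rose from 0.295 to 135 ± 2.82 CPM and Lin28a fell from 765 ± 30.4 to 37.5 ± 3.93 CPM. All 12 germline genes were higher (adjusted p = 1.33e-09; median log2 10.08, or 5.33 with 5 genes at their bound), Dazl at 292 ± 31.8 against 0.114 CPM. All 7 of the 2-cell-like genes tested were higher (adjusted p = 0.00134; adjusted p = 0.141 with an estimated correlation), Zscan4f at 15.8 ± 1.24 CPM against none, although reads of such close paralogs may be assigned uncertainly. Of 11 LIF-STAT3 pathway genes 7 were higher and 2 lower (adjusted p = 9.15e-07; adjusted p = 0.0792 with an estimated correlation), with Bcl3 at 81.3 ± 2.41 against 0.242 CPM and Stat3 at 132 ± 1.61 against 26.5 ± 1.14 CPM.

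Metabolic lists came next. Of 32 fatty acid oxidation genes 19 were higher in ESC and 6 lower (median log2 0.66, adjusted p = 0.000479; adjusted p = 0.209 with an estimated correlation). Slc25a20, the carrier of acylcarnitines, rose from 9.65 ± 1.33 to 50.6 ± 2.75 CPM, Ehhadh from 2.44 ± 0.336 to 14.9 ± 1.42 CPM, and Acadl fell from 13.5 ± 0.675 to 1.69 ± 0.231 CPM. The 23 genes of fatty acid synthesis, elongation and desaturation gave 11 higher and 9 lower (adjusted p = 0.356), with a median log2 of -0.05 but a mean of 0.14 and a test directed upward. Acacb rose from 18.7 ± 0.594 to 117 ± 1.65 CPM and Elovl4 fell from 25.1 ± 0.723 to 6.31 ± 1.25 CPM. In glycolysis 15 of 22 genes were lower and 4 higher (adjusted p = 3.76e-05; adjusted p = 0.209 with an estimated correlation). The lactate transporter Slc16a3 fell from 418 ± 64.1 to 2.81 ± 0.257 CPM and Pfkl from 434 ± 59.9 to 34.2 ± 1.47 CPM. The 9 genes of DNA methylation machinery divided 5 to 4 (adjusted p = 0.322; median log2 0.38 and mean 0.60, but a test directed downward), with Tet2 up from 6.76 ± 0.948 to 117 ± 6.27 CPM. Of the 6 sex-linked genes that track line identity, Ddx3y, Uty and Eif2s3y were above 25 CPM in every group. Kdm5d was 38.0 ± 3.06 CPM in EpiSC and 3.73 ± 0.966 CPM in ESC (list adjusted p = 0.553; median 0.05 and mean -0.06). In all, 5472 genes were higher and 6330 lower, 3297 and 3565 of them at least 2-fold, and 72.2% of genes had no overlap between the groups, against 10% by chance. The balance turned with RLE scaling, 6058 higher and 5678 lower, with DESeq2, 6130 and 5788, and with the 2 groups fitted alone, 5987 and 5624.

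What had changed by day 3 was asked with D3 against EpiSC. Trophoblast and BMP genes rose while Pou5f1, Sox2 and Nanog fell. The trophoblast regulator Cdx2, without a count in EpiSC, reached 30.8 ± 2.27 CPM, at least 164-fold higher (adjusted p = 2.78e-11). Hand1 rose from 0.856 to 458 ± 26.2 CPM (log2 difference 9.06 ± 0.38). Pou5f1 fell from 331 to 27.6 ± 10.8 CPM, Sox2 from 189 to 11.3 ± 0.958 CPM and Nanog from 40.9 to 4.23 ± 0.566 CPM (log2 differences -3.58 ± 0.39, -4.07 ± 0.30 and -3.27 ± 0.18; adjusted p = 2.75e-07, 1.71e-09 and 1.82e-11). Cpt1a had already reached 24.3 ± 0.799 CPM (log2 difference 3.91 ± 0.13, adjusted p = 3.69e-14), with Cpt2 at 46.1 ± 5.25 CPM (adjusted p = 0.495). Klf4 at 76.6 ± 7.36 CPM and Esrrb at 23.9 ± 0.0360 CPM were higher than in EpiSC (adjusted p = 3.27e-11 and 6.0e-08), and Zfp42 was at 1.12 ± 0.224 CPM.

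Of the primed genes, Fgf5 stood at 0.143 CPM at D3, Otx2 at 0.530 ± 0.172 CPM, Pou3f1 at 46.6 ± 6.32 CPM and Dnmt3b at 105 ± 6.53 CPM, all lower than in EpiSC (adjusted p at most 2.04e-09). The largest rises were Wnt6 and the WNT antagonist Dkk1, with no count in EpiSC and 115 ± 8.32 and 69.2 ± 0.985 CPM at D3. Next came Fxyd2, Sprr2a1 and Dlx2 at 39.3 ± 7.36, 38.3 ± 6.98 and 37.4 ± 3.13 CPM. Among the largest falls were Zic2 from 255 ± 7.31 to 1.04 ± 0.314 CPM, Kcnj3 from 86.3 ± 2.50 to 0.377 ± 0.0997 CPM, Foxd3 from 31.2 ± 2.52 to 0.143 CPM and Npcd from 13.8 CPM to none.

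All 14 BMP-SMAD targets and related regulators rose at D3 (median log2 4.05, adjusted p = 4.96e-18), among them Msx2 from 0.357 to 114 ± 1.11 CPM and Tfap2c from 2.10 to 202 ± 6.77 CPM. All 8 trophoblast genes rose (median log2 8.17, or 7.71 with 1 gene at its bound; adjusted p = 5.45e-11), including Krt7 at 271 ± 36.2 and Esx1 at 321 ± 17.1 CPM against 0.661 and 0.837 CPM. Naive genes were already higher for 15 of 21 and lower for 3 (median log2 3.11, or 1.86 with 4 genes at their bound; adjusted p = 0.00467; adjusted p = 0.525 with an estimated correlation). Shared pluripotency factors were lower for 9 of 11 and higher for 1 (adjusted p = 4.4e-05; adjusted p = 0.253 with an estimated correlation). Of 10 WNT targets 8 rose and Lef1 fell (adjusted p = 0.00112; adjusted p = 0.180 with an estimated correlation), with Axin2 at 92.4 ± 7.64 against 7.63 ± 1.45 CPM. The integrated stress response list fell, 7 of 8 genes lower (adjusted p = 4.57e-08), Chac1 from 99.1 ± 13.7 to 2.35 ± 0.534 CPM and Atf4 from 580 ± 34.9 to 136 ± 9.03 CPM. Primitive endoderm genes rose for 7 of 8, or 8 adjusted over the list alone (adjusted p = 9.21e-05; adjusted p = 0.0792 with an estimated correlation), Pdgfra from 0.510 to 23.2 ± 3.02 CPM. Of 13 feeder fibroblast markers 11 rose (median log2 3.48, or 2.92 with 1 gene at its bound; adjusted p = 0.00282; adjusted p = 0.241 with an estimated correlation), Col1a1 from 6.28 ± 2.26 to 404 ± 64.6 CPM. Imprinted genes went both ways, 10 up and 9 down (adjusted p = 0.00344; adjusted p = 0.141 with an estimated correlation). Igf2 rose from 60.3 ± 13.2 to 11970 ± 541 CPM, H19 from 8.81 ± 2.22 to 1738 ± 448 CPM and Peg10 from 141 ± 3.06 to 8004 ± 1362 CPM. Meg3 fell from 71.5 ± 7.61 to 2.95 ± 1.01 CPM. Igf2 alone took 1.238% of the deposited counts. Mesoderm and definitive endoderm genes (7 of 9 higher, adjusted p = 0.217) and mesenchymal genes (6 of 10 higher and 1 lower, or 2 lower adjusted over the list alone; adjusted p = 0.162) did not pass as lists. Eomes was still higher at 24.7 ± 2.12 against 9.89 ± 1.03 CPM and Snai1 at 69.1 ± 8.06 against 1.73 ± 0.637 CPM. Across all genes 5978 were higher and 5293 lower, 3674 and 2457 at least 2-fold, with no overlap for 68.1% against 10% by chance.

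How far the cells had moved by day 5 was asked against EpiSC in the same way. Cpt1a stood at 42.2 ± 1.44 CPM (log2 difference 4.71 ± 0.13, adjusted p = 1.54e-15). Cpt2 had risen to 92.0 ± 5.13 CPM (log2 difference 0.90 ± 0.12, adjusted p = 3.26e-06), opposite to its direction in ESC. Pou5f1 was at its lowest, 7.01 ± 4.64 CPM (log2 difference -5.56 ± 0.44, adjusted p = 1.83e-09), and Sox2 at 8.43 ± 2.87 CPM (adjusted p = 3.31e-10). Nanog at 16.8 ± 2.84 CPM was still below EpiSC (adjusted p = 9.0e-07). Klf4 at 106 ± 21.2, Esrrb at 14.1 ± 5.06 and Zfp42 at 3.49 ± 0.550 CPM were above it. Fgf5, Otx2, Pou3f1 and Dnmt3b were at 0.776 ± 0.368, 0.317 ± 0.119, 23.4 ± 4.47 and 38.3 ± 2.58 CPM, all lower (adjusted p at most 1.08e-09). The largest rises were the haemoglobin genes Hba-x and Hba-a1 at 105 ± 7.60 and 101.8 ± 65.7 CPM, and Slc16a12, Chdh and Muc15 at 82.3 ± 5.02, 77.8 ± 7.81 and 74.3 ± 6.98 CPM, none with a count in EpiSC. Hba-a1 has a close paralog. Kcnj3, Lhfpl4, St8sia3 and Kcnh8 had no count at D5 and 86.3 ± 2.50, 18.8 ± 2.88, 10.9 ± 1.10 and 10.1 ± 0.293 CPM in EpiSC.

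FGF-ERK response genes fell at D5, 11 of 13 lower and Fos alone higher (median log2 -4.80, adjusted p = 7.22e-12). Dusp6, a phosphatase of ERK, fell from 477 ± 33.3 to 0.769 ± 0.303 CPM, Spry4 from 72.4 ± 7.64 to 0.230 ± 0.0559 CPM and Etv4 from 96.9 ± 9.30 to 0.122 CPM. Of 32 fatty acid oxidation genes 25 rose and Cpt1c, Echs1 and Eci1 fell (median log2 0.95, adjusted p = 4.93e-05; adjusted p = 0.167 with an estimated correlation). Acadvl, which opens the mitochondrial oxidation of long-chain acyl-CoA, rose from 10.1 ± 1.51 to 70.3 ± 14.4 CPM. Genes of triglycerides and lipid droplets rose for 12 of 19 and fell for 2 (median log2 1.07, or 0.78 with 1 gene at its bound; adjusted p = 0.0306; adjusted p = 0.184 with an estimated correlation), Dgat2 from 20.7 ± 1.28 to 259.8 ± 10.3 CPM. Sphingolipid genes gave 17 higher and 6 lower of 25 (adjusted p = 0.0216; adjusted p = 0.209 with an estimated correlation), with Sgms2 at 48.9 ± 1.14 against 0.902 CPM. The 70 tested nuclear-encoded oxidative phosphorylation genes did not move as a list, 29 higher and 12 lower (adjusted p = 0.832). Epithelial markers gave 10 higher and 3 lower of 13 (adjusted p = 0.000374; adjusted p = 0.209 with an estimated correlation), Krt8 at 2452 ± 75.5 against 122 ± 14.03 CPM and Cldn4 at 1011 ± 55.0 against 5.39 ± 2.81 CPM. Neural progenitor genes gave 6 lower and none higher of 9 (median log2 -3.77, or -2.76 with 1 gene at its bound; adjusted p = 0.0173; adjusted p = 0.141 with an estimated correlation), Nes falling from 349 ± 46.3 to 15.4 ± 0.899 CPM. Of markers of other cell types, all 8 trophoblast genes were higher (adjusted p = 1.31e-05) and feeder fibroblast genes were 10 higher and 1 lower of 13 (adjusted p = 0.00332; adjusted p = 0.253 with an estimated correlation), Postn at 122 ± 13.5 against 0.444 ± 0.105 CPM. In all 6609 genes were higher and 6017 lower, 4489 and 3715 at least 2-fold, with no overlap for 75% against 10% by chance.

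At day 8, against EpiSC, the question was whether the naive genes had come up. Nanog had reached 279 ± 69.7 CPM (log2 difference 2.77 ± 0.16, adjusted p = 2.78e-11), Esrrb 187 ± 66.1 CPM (5.84 ± 0.31, adjusted p = 5.94e-12), Klf4 130 ± 39.4 CPM (adjusted p = 1.32e-12) and Zfp42 61.2 ± 23.9 CPM, at least 325-fold above EpiSC. Cpt1a was at 90.2 ± 18.6 CPM (log2 difference 5.80 ± 0.14, adjusted p = 1.57e-16) and Cpt2 at 81.2 ± 16.3 CPM (0.72 ± 0.12, adjusted p = 4.05e-05). Pou5f1 was still lower, 93.2 ± 45.8 CPM (adjusted p = 0.000196), as were Fgf5, Otx2, Pou3f1 and Dnmt3b at 1.38 ± 0.514, 0.796 ± 0.669, 9.54 ± 1.52 and 54.1 ± 8.51 CPM (adjusted p at most 2.88e-09). Sox2 at 116 ± 64.3 CPM was called lower (log2 difference -0.70 ± 0.27, adjusted p = 0.0247). That call was lost with DESeq2 at 0.0726, with the 2 groups fitted alone at 0.0722, without EpiSC replicate 3 at 0.0909, without D8 replicate 1 at 0.156 and without D8 replicate 2 at 0.116. Serpinb9f, Muc15, Slc16a12, Sgk2 and Chdh, without a count in EpiSC, rose most, to 113 ± 29.1, 88.9 ± 19.9, 75.3 ± 13.6, 71.2 ± 15.5 and 64.8 ± 6.18 CPM. Serpinb9f has close paralogs. Klhl4, Enpp2 and Vrtn fell from 288, 52.8 and 68.8 ± 0.494 CPM to 0.0353, 0.0367 and 0.0964 CPM. Npcd and Kcnh8 fell to no count.

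Naive genes were higher for 20 of 21, Gbx2 being lower (median log2 6.44, or 6.02 with 4 genes at their bound; adjusted p = 3.42e-10; adjusted p = 0.209 with an estimated correlation). All 12 germline genes were higher too (median log2 9.90, or 4.44 with 5 genes at their bound; adjusted p = 7.58e-05; adjusted p = 0.180 with an estimated correlation), Dazl at 145 ± 36.01 CPM. The same libraries held trophoblast genes, all 8 higher than in EpiSC (adjusted p = 0.000463; adjusted p = 0.0850 with an estimated correlation), with Krt7 at 403 ± 66.2 and Gata3 at 35.4 ± 4.51 CPM against 0.661 and 1.29 ± 0.147 CPM. They also held feeder fibroblast markers, 10 higher and 1 lower of 13 (adjusted p = 0.00656; adjusted p = 0.337 with an estimated correlation), with Col1a1 at 605 ± 92.9 and Postn at 164 ± 46.2 CPM. Fatty acid oxidation genes reached their widest extent, 29 higher and only Cpt1c and Echs1 lower of 32 (median log2 1.37, adjusted p = 4.19e-07; adjusted p = 0.108 with an estimated correlation), Ehhadh at 53.8 ± 10.7 and Slc25a20 at 69.5 ± 3.54 CPM. Genes of triglycerides and lipid droplets gave 13 higher and 2 lower of 19 (adjusted p = 0.0103; adjusted p = 0.141 with an estimated correlation), the droplet coat gene Plin4 at 48.2 ± 6.49 against 0.445 ± 0.349 CPM. Phospholipid genes gave 23 higher and 8 lower of 39, or 10 lower adjusted over the list alone, and did not pass as a list (adjusted p = 0.0793). Gpat3 still rose from 0.273 to 170 ± 29.5 CPM and Cds1 from 15.6 ± 0.834 to 99.8 ± 16.4 CPM. Across all genes 7434 were higher and 6048 lower, 5602 and 3619 at least 2-fold, with no overlap for 79% against 10% by chance.

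**Figure D2:**
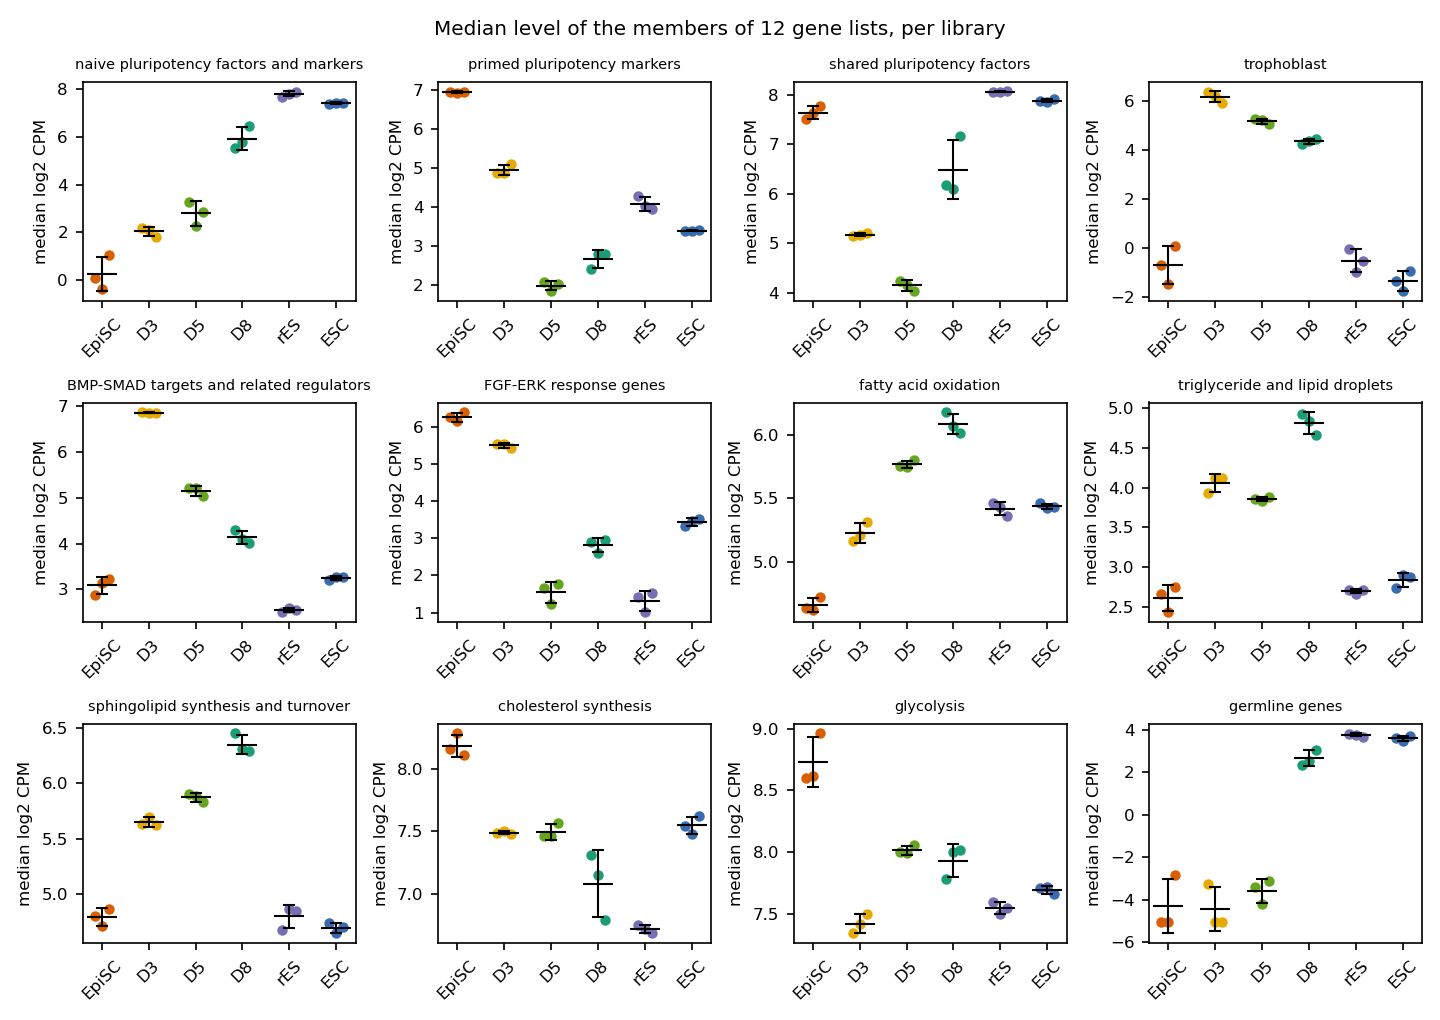
Median log2 CPM per library of 12 of the gene lists, with bars for mean ± SD, in EpiSC, D3, D5, D8, rES and ESC (n = 3 each). The trophoblast median was high at D3 to D8 and low at both ends, whereas the naive median was highest in rES and ESC.

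The cells obtained, rES, were set against their EpiSC start to ask what the whole passage had changed. Cpt1a reached 299.8 ± 11.7 CPM (log2 difference 7.54 ± 0.14, adjusted p = 5.46e-17), while Cpt2 ended below its start at 27.9 ± 3.10 CPM (log2 difference -0.82 ± 0.12, adjusted p = 1.13e-05). Nanog, Klf4 and Esrrb stood at 830 ± 5.11, 291 ± 12.4 and 671 ± 15.1 CPM (log2 differences 4.34 ± 0.18, 5.49 ± 0.22 and 7.68 ± 0.33), and Zfp42 at 265 ± 3.99 CPM was at least 1410-fold higher. Sox2 rose to 572 ± 4.82 CPM (log2 difference 1.60 ± 0.27, adjusted p = 4.45e-05) and Pou5f1 was back at 339 ± 8.15 CPM (adjusted p = 0.957). Fgf5 was at 0.127 ± 0.0292, Otx2 at 2.99 ± 0.0483, Pou3f1 at 4.29 ± 0.399 and Dnmt3b at 138 ± 4.12 CPM, all lower (adjusted p at most 6.58e-10). The largest rises beside Zfp42 and Nr0b1 were Rbmxl2 and the germ cell genes Stra8 and Sohlh2. Rbmxl2, Stra8 and Sohlh2 had no count in EpiSC and stood at 219.9 ± 5.63, 163 ± 12.3 and 146 ± 6.09 CPM in rES. Cnn1, Gpm6a and Cysltr1 went from 35.6 ± 1.01, 13.4 ± 0.483 and 13.3 ± 1.58 CPM to no count.

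In rES 20 of 21 naive genes were higher than in EpiSC (adjusted p = 4.72e-24; median log2 8.13, or 7.62 with 4 genes at their bound), 14 of 16 primed genes lower and Nodal higher (adjusted p = 2.76e-09), and all 12 germline genes higher (adjusted p = 4.87e-10), Dazl at 739 ± 19.3 CPM. Cholesterol synthesis genes were lower for 21 of 24 and higher for 2 (median log2 -1.10, adjusted p = 3.52e-06; adjusted p = 0.253 with an estimated correlation), Lss falling from 304 ± 25.6 to 47.6 ± 1.79 CPM and Sc5d from 68.7 ± 5.81 to 17.1 ± 1.80 CPM. Fatty acid oxidation genes were 22 higher and 9 lower of 32 (median log2 0.81, adjusted p = 0.000437; adjusted p = 0.209 with an estimated correlation). Here 5590 genes were higher and 6585 lower, 3502 and 3789 at least 2-fold, with no overlap for 75.2% against 10% by chance. Here too the balance turned, to 6327 higher and 5762 lower with RLE scaling, 6366 and 5871 with DESeq2 and 6377 and 5787 with the 2 groups fitted alone. Between ESC and rES, 9994 of the 11802 genes called in ESC against EpiSC were called in rES in the same direction, 4623 up and 5371 down, and 178 in the opposite one. Independent lists would share 1743 up and 2376 down. Both sets used the same EpiSC libraries, which simulated unchanged groups turned into a correlation of 0.5 but into at most 1 shared gene in 20 sets. The observed covariance of log2 differences was 9.133 against 0.09 in the simulation, so shared controls as simulated gave little of it. Their share in the real data was not measured, since 3 libraries cannot be divided into parts of at least 2.

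How rES differed from ESC was tested directly. Cpt1a was higher in rES, 299.8 ± 11.7 against 192 ± 3.11 CPM (log2 difference 0.64 ± 0.10, adjusted p = 0.000121), and Cpt2 was 27.9 ± 3.10 against 26.4 ± 0.417 CPM (adjusted p = 0.666). Sox2 was higher, 572 ± 4.82 against 279 ± 29.0 CPM (1.03 ± 0.27, adjusted p = 0.00628), as were Pou3f1 (1.46 ± 0.19, adjusted p = 1.35e-05) and Dnmt3b, 138 ± 4.12 against 71.5 ± 2.13 CPM (0.95 ± 0.09, adjusted p = 3.45e-07). Pou5f1 (adjusted p = 0.975) and Klf4 (adjusted p = 0.735) were not called. Esrrb at 671 ± 15.1 against 782 ± 27.6 CPM and Zfp42 at 265 ± 3.99 against 318 ± 4.32 CPM were not called either (adjusted p = 0.526 and 0.314), but passed with the 2 groups fitted alone at 0.000535 and 0.000166. Otx2 gave 0.0914, and 0.00866 with the 2 groups alone and 0.0261 with counts divided by 4. Fgf5 was at or under the floor in both. Nanog was called lower, 830 ± 5.11 against 1114 ± 24.7 CPM (log2 difference -0.43 ± 0.15, adjusted p = 0.0391). RLE scaling at 0.0553 and a replicate block at 0.0552 ended that call, as did leaving out rES replicate 1, 2 or 3 at 0.0920, 0.0877 and 0.0845 or ESC replicate 1, 2 or 3 at 0.0785, 0.0688 and 0.0941.

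Magea8 rose most in rES, 15.6 ± 1.13 against 1.47 ± 0.0907 CPM (3.41 ± 0.23). Ptprtos followed at 14.2 ± 1.85, Tuba3b at 26.9 ± 0.983, Pdzrn4 at 11.7 ± 0.991 and Atp12a at 28.3 ± 3.81 CPM against 1.54 ± 0.236, 3.59 ± 0.653, 1.66 ± 0.492 and 4.42 ± 0.790 CPM. Lox, which cross-links collagen, had no count in rES and 15.1 ± 2.10 CPM in ESC, at least 77.1-fold lower. Col3a1 was 0.116 against 19.7 ± 2.54 CPM, Thbs1 0.602 ± 0.1499 against 17.4 ± 2.66 CPM and Col1a1 2.92 ± 0.941 against 79.3 ± 14.5 CPM. Among 13 feeder fibroblast markers 7 were lower in rES, 8 adjusted over the list alone, and none higher (adjusted p = 7.0e-12; median log2 -4.76, or -1.20 with 5 genes at their bound). FGF-ERK response genes gave 7 lower and 2 higher of 13 (adjusted p = 6.9e-07; median -0.86, or -0.60 with 1 gene at its bound). Spry4 was 0.253 ± 0.134 against 11.6 ± 1.46 CPM, Egr1 0.567 ± 0.408 against 8.95 ± 0.876 CPM and Dusp6 2.50 ± 0.444 against 7.66 ± 1.23 CPM. Spry1 and Etv5 were the 2 higher.

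Targets of p53 were higher in rES for 8 of 10 and lower for none (median log2 0.66, adjusted p = 2.12e-06), the cell cycle inhibitor Cdkn1a at 275 ± 1.58 against 149.8 ± 3.77 CPM and the apoptosis gene Bbc3 at 32.8 ± 0.514 against 10.5 ± 1.82 CPM. Cholesterol synthesis genes were lower for 18 of 24, 19 adjusted over the list alone, and Ebp higher (adjusted p = 1.47e-08; adjusted p = 0.184 with an estimated correlation), Mvd at 34.5 ± 1.64 against 75.7 ± 7.77 CPM. Fatty acid synthesis, elongation and desaturation genes gave 13 lower and 2 higher of 23, or 15 and 3 adjusted over the list alone (adjusted p = 0.00332; adjusted p = 0.219 with an estimated correlation), Scd1 at 529 ± 16.1 against 873 ± 36.3 CPM. WNT targets were higher for 7 of 10 (adjusted p = 0.000283; adjusted p = 0.141 with an estimated correlation), Lef1 at 27.9 ± 1.12 against 7.52 ± 1.20 CPM and Axin2 at 95.8 ± 2.94 against 55.8 ± 1.90 CPM. Imprinted genes were 9 lower and 4 higher of 19 (adjusted p = 0.00312; adjusted p = 0.151 with an estimated correlation), Peg10 at 18.6 ± 1.37 against 301 ± 13.0 CPM. The 2-cell-like genes were lower for 3 of 7, or 4 adjusted over the list alone (adjusted p = 0.0342; adjusted p = 0.292 with an estimated correlation). In all 2736 genes were higher and 3141 lower, but only 776 and 730 at least 2-fold, with no overlap for 53.7% against 10% by chance. More were higher than lower with RLE scaling, 3103 and 2835, with DESeq2, 3497 and 3175, and with the 2 groups fitted alone, 3932 and 3916.

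Steps within the transition were then tested between neighbouring days. From D3 to D5 the FGF-ERK genes fell without exception, 13 of 13 (median log2 -4.02, adjusted p = 1.17e-22). Spry4 went from 46.5 ± 3.83 to 0.230 ± 0.0559 CPM (log2 difference -7.65 ± 0.23, adjusted p = 5.63e-14), Etv4 from 58.1 ± 10.3 to 0.122 CPM and Dusp6 from 46.2 ± 0.471 to 0.769 ± 0.303 CPM. BMP-SMAD genes were lower for 7 of 14 and higher for 4, or 8 and 4 adjusted over the list alone (adjusted p = 0.000425), with Msx1 down from 118 ± 1.96 to 2.03 ± 0.438 CPM and Id3 from 252 ± 19.05 to 31.6 ± 1.96 CPM. Mesoderm and definitive endoderm genes fell for 6 of 9, or 7 adjusted over the list alone (adjusted p = 0.00197; median log2 -4.27, or -1.61 with 3 genes at their bound), Eomes from 24.7 ± 2.12 to 0.474 ± 0.224 CPM and Wnt3 from 17.5 ± 2.34 to 0.699 ± 0.131 CPM. Mesenchymal genes fell for 8 of 10 (adjusted p = 0.00123; adjusted p = 0.0939 with an estimated correlation), Twist1 from 21.7 ± 6.28 to 2.07 ± 0.721 CPM. Of the trophoblast list, Hand1 fell from 458 ± 26.2 to 39.7 ± 3.23 CPM and Cdx2 from 30.8 ± 2.27 to 1.77 ± 0.665 CPM, with 4 genes lower and 3 higher of 8 (adjusted p = 0.109). Fatty acid oxidation genes rose for 24 of 32 and fell for 1 (median log2 0.83, adjusted p = 1.03e-06; adjusted p = 0.0945 with an estimated correlation), Ehhadh from 8.52 ± 1.24 to 33.6 ± 2.95 CPM and Acadl from 5.31 ± 0.750 to 19.12 ± 3.85 CPM. Oxidative phosphorylation genes gave 38 higher and 4 lower of 70 (median log2 0.32, adjusted p = 0.0262; adjusted p = 0.654 with an estimated correlation). The haemoglobin genes Hba-a1, Hba-x, Hbb-bh1 and Hbb-y and the placental fusion gene Synb rose most, to 101.8 ± 65.7, 105 ± 7.60, 30.8 ± 7.46, 11.4 ± 3.13 and 141 ± 15.6 CPM from at most 0.381 CPM. Vgf fell from 134 ± 19.5 to 0.776 ± 0.370 CPM, Crabp1 from 42.0 ± 8.16 to 0.319 ± 0.219 CPM and Hoxc9 from 14.2 ± 2.88 to 0.119 CPM. In this step 5251 genes were higher and 5186 lower, 2355 and 2695 at least 2-fold, with no overlap for 64.6% against 10% by chance. Slightly more were lower with RLE scaling, 5217 higher and 5222 lower, with DESeq2, 5336 and 5375, with the 2 groups fitted alone, 4999 and 5225, and without D3 replicate 2, 4818 and 4848.

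From D5 to D8 the question was which genes came back. Nanog rose from 16.8 ± 2.84 to 279 ± 69.7 CPM (log2 difference 4.05 ± 0.17, adjusted p = 1.53e-11), Pou5f1 from 7.01 ± 4.64 to 93.2 ± 45.8 CPM (3.74 ± 0.41, adjusted p = 7.16e-07) and Sox2 from 8.43 ± 2.87 to 116 ± 64.3 CPM (3.79 ± 0.30, adjusted p = 1.82e-08). Naive genes rose for 20 of 21 (median log2 3.35, adjusted p = 6.16e-22; adjusted p = 0.0544 with an estimated correlation), Dppa5a from 20.1 ± 6.10 to 442 ± 141 CPM. Shared pluripotency factors rose for 10 of 11, Lin28a falling (adjusted p = 1.12e-09; adjusted p = 0.133 with an estimated correlation). D8 replicate 3 stood above replicates 1 and 2 in both lists, with median log2 CPM of 6.45 against 5.52 and 5.81 for naive genes and 7.18 against 6.19 and 6.10 for shared factors. All 12 germline genes rose (median log2 6.87, or 5.12 with 3 genes at their bound; adjusted p = 8.97e-16), Dazl from 0.858 ± 0.181 to 145 ± 36.01 CPM and Hormad1 from none to 24.8 ± 9.78 CPM. FGF-ERK genes rose for 8 of 13 (adjusted p = 8.36e-06), Etv5 from 12.1 ± 1.89 to 135 ± 43.6 CPM. BMP-SMAD genes fell for 12 of 14 (adjusted p = 0.000186), Id1 from 40.2 ± 3.31 to 16.3 ± 3.35 CPM. Cholesterol synthesis genes fell for 16 of 24 (median log2 -0.42, adjusted p = 3.81e-05; adjusted p = 0.306 with an estimated correlation), Idi1 from 162 ± 13.2 to 84.8 ± 9.75 CPM. Cpt1a rose 1.10 ± 0.10 in log2 (adjusted p = 1.53e-07). Sohlh2, Nptx2, Cdyl2 and Tuba3a, at most 0.328 CPM at D5, reached 22.9 ± 9.95, 15.2 ± 5.54, 14.03 ± 7.20 and 58.1 ± 17.03 CPM. Phf19 fell from 91.6 ± 0.309 to 6.92 ± 1.03 CPM, Hbb-bh1 from 30.8 ± 7.46 to 3.48 ± 0.835 CPM, Cers3 from 22.8 ± 1.27 to 3.57 ± 1.38 CPM and Dok4 from 79.9 ± 5.98 to 13.8 ± 2.80 CPM. Of 4397 genes higher and 3868 lower, 2551 and 616 were at least 2-fold, with no overlap for 55.2% against 10% by chance. RLE scaling raised the share higher from 53.2% to 59.2%.

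The last step, rES against D8, asked what was lost on the way to the final cells. Epithelial genes fell for 11 of 13 and rose for none (median log2 -4.25, adjusted p = 3.92e-14). The keratins Krt18 and Krt8 went from 1391 ± 206 and 2174 ± 311 CPM at D8 to 1.67 ± 0.107 and 7.86 ± 0.462 CPM (log2 differences -9.70 ± 0.15 and -8.11 ± 0.14). Imprinted genes gave 10 lower and 4 higher of 19 (adjusted p = 7.58e-05; adjusted p = 0.0716 with an estimated correlation), Igf2 falling from 10750 ± 1307 to 1.67 ± 0.182 CPM and Peg10 from 14610 ± 3114 to 18.6 ± 1.37 CPM. Trophoblast genes were lower for 6 of 8, Cdx2 being higher (adjusted p = 0.00124; adjusted p = 0.209 with an estimated correlation), Krt7 at 1.13 ± 0.454 against 403 ± 66.2 CPM. Feeder fibroblast genes were lower for 10 of 13 (adjusted p = 0.000425; adjusted p = 0.209 with an estimated correlation; median log2 -7.69, or -4.11 with 5 genes at their bound), Dcn at none against 56.4 ± 22.7 CPM. Lipid droplet genes were lower for 14 of 19 and higher for 2 (adjusted p = 0.000425; adjusted p = 0.0682 with an estimated correlation), Dgat2 at 4.78 ± 0.272 against 206 ± 31.2 CPM. Phospholipid genes were lower for 25 of 39 and higher for 8, or 26 and 8 adjusted over the list alone (adjusted p = 0.00361; adjusted p = 0.327 with an estimated correlation), Gpat3 at 3.73 ± 0.219 against 170 ± 29.5 CPM. Serpinb9e, Synb, the lipid regulator Pparg, Klk6 and Olr1 had no count in rES and 289.8 ± 73.8, 206 ± 46.8, 175 ± 43.2, 145 ± 39.9 and 125 ± 24.02 CPM at D8. Tlx2 rose most, from 1.10 ± 0.701 to 30.8 ± 2.09 CPM. Akr1cl, Pdzrn4 and Gstp1 rose to 17.4 ± 0.565, 11.7 ± 0.991 and 44.1 ± 17.1 CPM. In all 5739 genes were higher and 6738 lower, 3085 and 4805 at least 2-fold, with no overlap for 76.9% against 10% by chance.

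Where each group lay between the reference states was read from the 6862 genes at least 2-fold different between ESC and EpiSC, with EpiSC set at 0% and ESC at 100%. D3 lay at 27.9% (SD 0.26), D5 at 40.8% (SD 0.84), D8 at 67.0% (SD 2.71) and rES at 98.4% (SD 0.15). D8 replicate 3 stood apart at 70.17%, against 65.42% and 65.54% for replicates 1 and 2. The intermediate days also stood off the line, by 59.2%, 68.4% and 65.4% of its length at D3, D5 and D8 and by 27.8% in rES. Of the 6862 genes 1030, or 15%, were at least 2-fold different between rES and ESC, counting both directions.

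**Figure D3:**
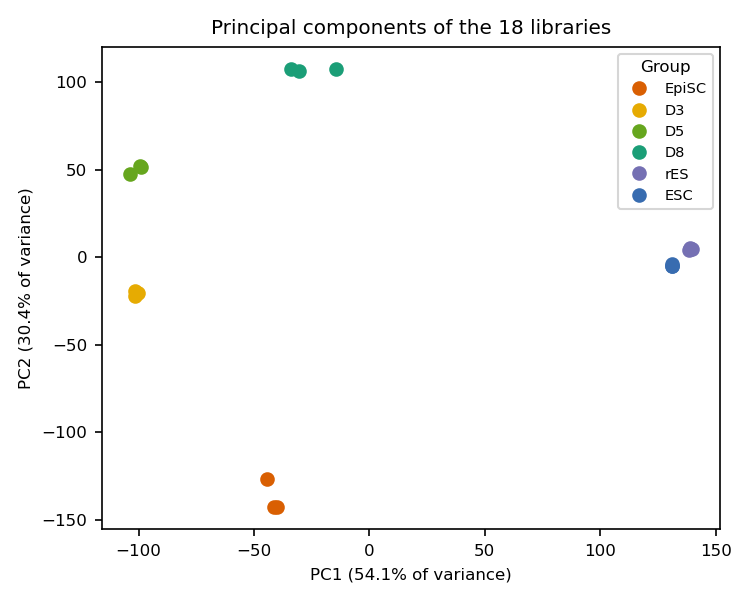
Principal components of log2 CPM over the 2000 most variable genes, 1 point per library, coloured by group (n = 3 each). PC1 held 54.1% and PC2 30.4% of the variance, and rES lay next to ESC while D3, D5 and D8 lay apart from both ends.

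Genes at an intermediate day outside both ends, at least 2-fold from EpiSC and from rES, were counted last. Raised genes numbered 3997, with 2082 at D3, 2825 at D5, 3057 at D8 and 1322 at all 3 days. Lowered genes numbered 2633, with 886, 1838, 1443 and 264. Ranked by the smaller of their differences from EpiSC and from rES, among genes with at least 10 CPM at their highest day, the most raised were Hba-x, Hba-a1, Muc15, Serpinb9d and Fam90a1b, with no count in EpiSC, rES or ESC and highest levels of 105 and 101.8 CPM at D5 and 88.9, 32.8 and 30.9 CPM at D8. Hba-a1, Serpinb9d and Fam90a1b belong to families of near-identical genes. By the same rank, among genes with at least 10 CPM in both EpiSC and rES, Zic2 led the lowered genes, from 255 CPM in EpiSC to 0.519 CPM at D5 and back to 77.8 CPM in rES. Gbx2 followed at 47.6, 0.328 and 61.1 CPM, the fatty acid transporter Slc27a2 at 76.1, 0.218 and 29.1 CPM, Zic5 at 61.6, 0.174 and 22.6 CPM and Maneal at 10.7, 0.102 and 12.4 CPM. Raised genes held all 8 trophoblast, all 8 primitive endoderm and all 13 feeder fibroblast genes, where 22.8% of all genes were raised (Fisher's exact test, adjusted p = 5.23e-05, 5.23e-05 and 1.27e-07). They also held 10 of 14 BMP-SMAD genes (adjusted p = 0.000861), 10 of 19 lipid droplet genes (adjusted p = 0.0182) and 10 of 19 imprinted genes (adjusted p = 0.0182). Fisher's test takes list members as independent. Against EpiSC the calls ended at D3, D5 and D8 for primitive endoderm (adjusted p = 0.0792, 0.116 and 0.0792 with an estimated correlation), feeder fibroblast (0.241, 0.253 and 0.337) and imprinted genes (0.141, 0.253 and 0.230). They ended at D5 and D8 for lipid droplet genes (0.184 and 0.141), at D3 and D5 for shared factors (both 0.253), and at D8 alone for trophoblast (0.0850) and BMP-SMAD genes (0.0789). Fatty acid oxidation genes were raised for 12 of 32 (adjusted p = 0.137). Oxidative phosphorylation genes were raised for 0 of 70, a smaller share than of all genes (adjusted p = 3.44e-07). They were also fewer among the lowered genes, 2 of 70 (adjusted p = 0.0149). Lowered genes, 15.0% of all, held 11 of 16 primed genes (adjusted p = 5.19e-05), 8 of 11 shared pluripotency factors (adjusted p = 0.000398) and 7 of 13 FGF-ERK genes (adjusted p = 0.0122).

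**Figure D4:**
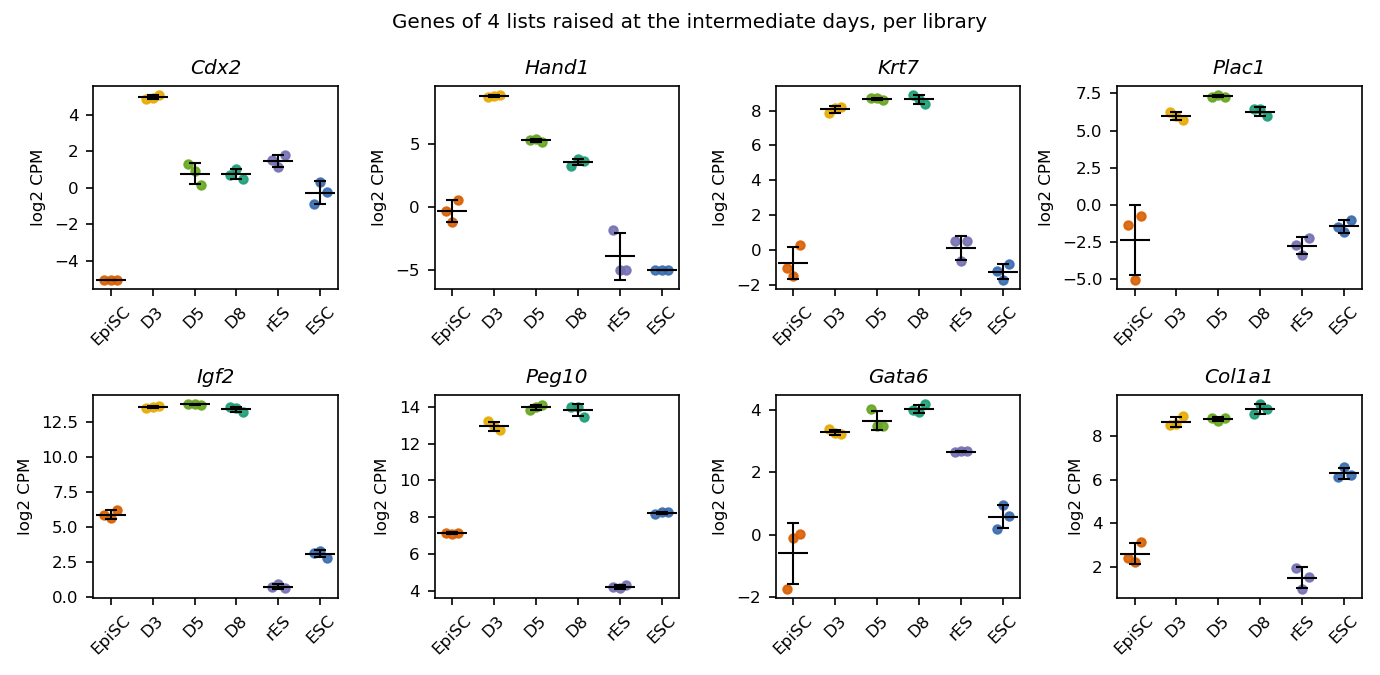
Log2 CPM of Cdx2, Hand1, Krt7, Plac1, Igf2, Peg10, Gata6 and Col1a1, 1 point per library with bars for mean ± SD, in EpiSC, D3, D5, D8, rES and ESC (n = 3 each). Igf2 stood at 60.3 CPM in EpiSC, 11970 CPM at D3 and 1.67 CPM in rES.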

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

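The tests of explanations and of other splits in this part were chosen only after the result was seen, except the one on the size of D8 replicate 2, while the gene and list comparisons with EpiSC, between rES and D8 and between rES and ESC were planned.

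At D8 the same libraries held trophoblast and naive genes, such as Krt7 at 403 ± 66.2 CPM and Nanog at 279 ± 69.7 CPM. If each of the other 5 groups were 1 uniform state, a mixed sample of those states alone could not place genes above all of them. Yet 415 genes were at least 2-fold higher at D8 than in each other group. A mixture of 5 uniform states is therefore not enough. Each group mean may itself average over mixed cells, so these genes do not show that D8 held a state of its own. A mixed sample of uniform rES-state and D5-state cells would give all genes absent at D5 and in EpiSC the same D8 to rES ratio. The log2 ratios of 141 such genes had a median of -2.07. Their median absolute deviation, scaled to be read as an SD, was 0.75. Between the D8 libraries the median SD of these genes was 0.49. The ratios thus varied somewhat more than the libraries did, but these measures differ and either group may itself be mixed, so such a mixture is not excluded. Library size is an unlikely cause, since 28 of 28 trophoblast and naive genes (100%) stayed called without D8 replicate 2.

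Feeder fibroblast genes were higher at D3, D5 and D8 than in EpiSC, calls that ended with an estimated correlation (adjusted p = 0.241, 0.253 and 0.337 with an estimated correlation). They were higher at D8 than in rES (adjusted p = 0.209 with an estimated correlation) and higher in ESC than in rES (adjusted p = 0.0252 with an estimated correlation). If RNA from feeder cells of 1 kind were the only source at D8 and in ESC, the D8 to ESC ratio would be alike for all markers. Over 7 markers it ran from -0.05 for Pdgfrb to 5.93 for Postn in log2, an SD 9.4 times the median standard error, so that source alone is unlikely. In rES against ESC, 28 other fibroblast transcripts were lower as a list (median log2 -0.94, 16 lower and 2 higher; adjusted p = 0.0197 with an estimated correlation), as a feeder source in ESC would give, but the list holds Lox and Thbs1, among the largest falls already seen, so that source stays open.

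FGF-ERK response genes were lower at D5 than at D3 and lower in rES than in ESC. Handling at harvest, which moves immediate-early genes, is unlikely to be the whole cause at D5, because feedback and ETS genes, 9 of 9 lower, had a median log2 difference of -4.34 against -1.40 for the immediate-early genes. In rES against ESC the feedback and ETS genes had a median of only -0.20, 4 lower and 2 higher of 9, against -2.44 for the immediate-early genes. The 4 lower were Spry4 at -5.51, Dusp6 at -1.61, Etv4 at -1.37 and Spry2 at -0.6. The 2 higher were Etv5 at 0.49 and Spry1 at 0.33. Of the 4 immediate-early genes 3 were lower, and Fosl1 was under the floor in both groups. Falls were thus not confined to immediate-early genes. Handling may still be a cause in rES against ESC, and these data cannot tell.

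Other results went against the passage from EpiSC to rES. Genes at least 2-fold from EpiSC in one direction at an intermediate day and in the other in rES numbered 840 at D3 (622 first higher and 218 first lower), 958 at D5 (638 and 320) and 687 at D8 (662 and 25). Against EpiSC, epithelial markers were higher for 8 and lower for 3 of 13 at D8 (adjusted p = 0.00848; adjusted p = 0.348 with an estimated correlation), and lower for 9 and higher for 3 in rES (adjusted p = 2.12e-07; adjusted p = 0.0858 with an estimated correlation). In rES against D8 the list was lower (adjusted p = 3.92e-14). Cpt2 was above EpiSC at D5 and D8 and below it in rES, with log2 differences from rES of 1.72 and 1.54. Sox2 was below EpiSC at D3, D5 and D8 and above it in rES, with log2 differences from rES of -5.67, -6.08 and -2.30, and the D8 call against EpiSC was among those that leaving out a library ended. Nanog was below EpiSC at D3 and D5, with log2 differences from rES of -7.62 and -5.62.

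Every split of the 6 libraries of a comparison other than the real one gave far fewer calls. The real grouping was the 1 of 10 splits with most calls each time: 11802 against at most 1 for ESC and EpiSC, 11271 against 10 for D3 and EpiSC, 12626 against 6 for D5 and EpiSC, and 13482 against 0 for D8 and EpiSC. For rES and EpiSC it was 12175 against 4, for rES and ESC 5877 against 5, for D5 and D3 10437 against 4, for D8 and D5 8265 against 2 and for rES and D8 12477 against 0. Each other split put libraries of both groups on both sides, which turned the group difference into spread within a side. Their few calls were thus fixed in advance and do not measure false calls. With 10 splits no share under 0.05 can be reached.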

How the results depend on the processing

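The division of counts by 4 and the omission of day 8 were chosen only after the data were seen; the other settings were chosen before the data were examined.

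All 21 gene counts stayed within 1.5-fold under every setting in which they were counted. So did each of 147 counts with a library left out, and the 2 transient counts with D3 and D5 alone as intermediate days. With 2 groups fitted alone, 18 of the 21 were counted. The balance of higher to lower genes turned with RLE scaling, DESeq2 and 2 groups fitted alone for ESC against EpiSC, rES against EpiSC, rES against ESC and D5 against D3. D3 lay at 28.7% and rES at 98.1% of the way from EpiSC to ESC with all tested genes on the axis, and at 28.5% and 97.1% with a prior count of 0.5. Leaving out a library moved D8 between 65.5% and 67.9%. Of 1087 results for named genes 1033 were the same under all settings. DESeq2 ended 12 calls and added 5, RLE scaling ended 5 and added 4, 2 groups fitted alone ended 6 and added 10 of 1084, and division by 4 ended 0 and added 8. A replicate block ended 5 and added 1, no filter ended 3, a stricter filter added 4 and removal of structural RNAs added 1. Leaving out a library ended 87 and added 7 of 6522.

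Gene lists depended more on the setting: 59 of 261 list results were the same under all. An estimated correlation ended 92 calls and added 0. Limma's fry ended 0 and added 110, but it asks whether members changed at all, not whether they changed more than other genes. The count of 59 includes that different question. Division by 4 ended 6 and added 2, a replicate block ended 14 and added 2, no filter ended 8 and added 5, a stricter filter ended 6, RLE scaling ended 1 and added 1, and a library left out ended 13 and added 15 of 1566. List results without a call under an estimated correlation are therefore weaker than those of single genes.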

Other observations

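The genes and the list in this part were chosen only after the data were seen, and so were the tests on them.

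Interferon response genes were raised at D5 and D8. Against EpiSC, 12 of 22 were already higher at D3 and 4 lower (median log2 2.25, camera adjusted p = 0.0448; adjusted p = 0.297 with an estimated correlation). At D5 21 were higher than in EpiSC and none lower (median log2 5.83; adjusted p = 0.00375 with an estimated correlation). Of 22 such genes, 22 were higher at D5 than at D3 (median log2 3.66, adjusted p = 9.25e-27) and 22 higher at D8 than in EpiSC (median log2 7.70; adjusted p = 0.00375 with an estimated correlation). In rES 21 were lower than at D8 and 1 higher (adjusted p = 6.65e-11). Against EpiSC, 13 were higher in rES and 3 lower (median log2 2.20, adjusted p = 0.000129; adjusted p = 0.107 with an estimated correlation), and 12 were higher in ESC and 3 lower (median log2 1.63, adjusted p = 7.22e-05; adjusted p = 0.1 with an estimated correlation). In rES against ESC 5 were higher and 4 lower (adjusted p = 0.998). Usp18 averaged 0.245 CPM in EpiSC, 94.3 CPM at D5, 182 ± 23.3 CPM at D8 and 0.170 CPM in rES, and Ifit1 averaged 0.145, 19.8, 56.5 and 0 CPM. Isg15, Oasl2 and Rsad2, which raised the question and were left out of the list, were at 106, 181 and 255 CPM at D8.

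Genes highest at D8 among all groups included Gjb2 at 3314 CPM, against 1102 CPM at D5, and Ctsb, Tgm2, Txnip, Lgals3bp, Lipg and Serpinb9e at 1921, 1172, 875, 528, 414 and 289.8 CPM. Of 22 interferon genes 9 were at least 2-fold higher at D8 than in every other group, as were 415 of all 17545 tested genes. Against D5, 17 of the 22 were higher at D8 and 0 lower (median log2 1.11). That list call ended with an estimated correlation (camera adjusted p = 3.91e-05, and 0.11 with an estimated correlation).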
